A study of Drosophila melanogaster with 4 samples.

How the data were processed

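Hi-C, which ligates DNA ends that lie close together in the nucleus and sequences the junctions, was carried out on sorted cells of Drosophila melanogaster embryos. Per the labels' protocols, embryos of a line carrying the rat surface protein CD2 under control of twist were collected for 2.25 h and aged for 11 h at 18 °C. Dissociated cells were stained for CD2, fixed for 10 min in 1% formaldehyde and sorted into a CD2-positive population (mesoderm) and a CD2-negative population (non-mesoderm). Chromatin was cut with DpnII, the ends were filled with a biotinylated nucleotide and ligated in the intact nucleus, and junction fragments of 200 to 300 bp were captured, per the labels' protocols. Paired-end reads of 50 bp were obtained on an Illumina instrument, according to the series design. Each population had 2 libraries, so 4 libraries were made in all. Nothing in the labels says whether the 2 libraries of a population came from separate collections of embryos.

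The values used here are the authors' deposited lists of changed contacts, 1 for each of 2 comparisons of a single mesoderm library with a single non-mesoderm library. Comparison 1 set mesoderm replicate 1 against non-mesoderm replicate 2. Comparison 2 set mesoderm replicate 2 against non-mesoderm replicate 1. The comparisons have no library in common, so the second served as the replicate check of the first. This check does not cover a difference that runs the same way in both comparisons, such as the depth described below. BWA, bedtools and genome build dm3 are named per the submitters' processing notes. The names of the deposited lists refer to chromoR, a program for differential Hi-C contacts, and to significant changes. The threshold, the mapping filters, the removal of duplicates and the library totals are not given in the sources used here. Contact maps of single libraries were not analysed here.

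The deposited lists have no header, so the meaning of their columns was read from the values. Each entry is a pair of 1000 bp bins on 1 chromosome with a score of the change, a whole number for each library and an adjusted number for each library. The score was never negative. The whole number is called the contact value here. It was even in every entry of both lists, as it would be if each read pair were entered at both of its ends, so a contact value of 8 is read here as 4 read pairs. Within a chromosome and library the adjusted number was nearly proportional to the contact value, with a small offset. It lay slightly below 0 where the contact value was 0. Every pair was written in both orientations with the same values and was counted once. No list held pairs between chromosomes or pairs of a bin with itself. Neither list gave p or q values.

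A pair is called mesoderm-higher where the first library of its comparison had the larger adjusted number, and non-mesoderm-higher otherwise. That the first number belongs to the mesoderm library rests on the order in the lists' names alone, so this direction is likely but not settled. The plan fixed before the data were examined gave directions only if a header or the values settled them. Directions are nevertheless printed here, since sizes, overlaps and agreement between comparisons hold with the sign turned as well.

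The depth of the libraries is unknown. The adjusted number per unit of contact value gave a proxy for relative depth. It was 1.62 times as large in the non-mesoderm as in the mesoderm library of comparison 1 (median over 5 chromosome arms, range 1.59 to 1.66) and 4.23 times as large in comparison 2 (range 4.21 to 4.30). By this proxy the non-mesoderm library was the shallower one in both comparisons. The lowest contact value with which a pair was listed differed accordingly. It was 8 for mesoderm-higher and 6 for non-mesoderm-higher pairs in comparison 1, and 12 and 4 in comparison 2. Depth as read from the proxy cannot be told apart from population in these lists, and agreement between the comparisons does not separate the 2. How the adjusted number was computed is not known, so the proxy may not measure depth alone.

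Bin pairs present in both lists were counted as shared and set against 1000 circular shifts of list 1 within each chromosome. Both ends of a pair moved together, which kept the distance. The one-sided permutation p is the share of shifts with a count, or a share of equal direction, at least as large as observed, the observed order included. Because shifts do not keep the number of listed pairs at a bin, the overlap was also computed from each bin's number of pairs in list 1 and the distance. For 100 kb and below, the overlap of independent lists (n1 × n2 / N) was computed from the number of possible bin pairs. Recurrence was further compared between pairs matched on chromosome, distance band and contact value with a Mantel-Haenszel rate ratio. Its 95% interval came from leaving out 1 Mb windows in turn. The share of mesoderm-higher pairs was compared between comparisons in 1 Mb windows with at least 50 listed pairs, each pair counted at both of its bins. Permutation p values for these correlations came from 10000 rotations or mirrored rotations of the windows within each arm, two-sided, with Benjamini-Hochberg adjustment over 21 relations. Intervals of shares are 95% Wilson intervals and cover counting error only, since bin pairs are not independent observations. With 2 comparisons a sign test cannot reach p below 0.05, and no test across replicates was run.

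Named regions were chosen by a rule fixed before the data were examined. They are the 10 bins with most shared mesoderm-higher pairs and the 10 with most shared non-mesoderm-higher pairs, adjacent bins merged and ties ordered by summed change and position. To these come the 5 shared pairs of each direction whose smaller change of the 2 comparisons was largest. Lists of mesodermal, neural, ectodermal and other genes had been fixed beforehand as well, but they were not run. The gene table at hand follows a later genome release than dm3, and coordinates were not converted, so regions are given by dm3 position without gene names.

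The overlap counts, the bin-weighted expectation and the matched rate ratio were tested on simulated data with the chromosome spans and distances of the real lists. With no planted pairs the simulated overlap of comparison 1 and comparison 2 was 1.00 times the shifted one. With 2000 planted pairs the excess over the shifts was 1844 pairs. In simulated lists with uneven bins and no planted pairs the overlap was 2.60 times the shifted one and 1.03 times the bin-weighted one. Planted rate ratios of 1 and 2 were recovered as 0.945 (95% interval 0.757 to 1.18) and 1.90 (1.47 to 2.46).

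Alternatives were larger changes only, removal of chromosome 4, lists cut to equal length, ends within 1 bin and ends shifted independently. Others were counts divided by the listed pairs at a bin, removal of neighbouring bins and each comparison alone. Chosen after seeing the data were the same minimum contact value for both directions, the bin-weighted expectation, the matched rate ratio, the use of neighbouring-bin removal beyond the distance result, and all windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.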

Results

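Chromatin contacts were compared between mesoderm and the remaining cells of Drosophila embryos, which were separated by sorting for a CD2 marker driven by twist, a master regulator gene of mesoderm. The title of the series concerns DNA elements that silence transcription in some cells and enhance it in others, and the comparison asks which contacts differ between a tissue and the rest of the embryo. Each population was represented by 2 Hi-C libraries. The material was the authors' lists of changed contacts from 2 comparisons of 1 mesoderm library with 1 non-mesoderm library. Comparison 1 held 185163 bin pairs and comparison 2 held 824678 bin pairs, all within chromosomes and at 1 kb resolution. Positions are those of genome build dm3. Listed pairs lay between 5001 and 22985000 on 2L, 3001 and 21145000 on 2R, 19001 and 23012000 on 3L, 4893001 and 27899000 on 3R, 7001 and 22422000 on X, and 68001 and 1250000 on chromosome 4. Sequence outside these limits was not analysed here.

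Nearly every listed contact was present in 1 library of its comparison and listed at 0 in the other. This held for 185157 pairs (99.9968%) of comparison 1 and 824097 pairs (99.9295%) of comparison 2. The changes were carried by small contact values. A pair is called mesoderm-higher or non-mesoderm-higher after the library with the larger value; which library is which rests on their order in the lists' names, so directions are likely, not settled. The median contact value in the higher library was 10 for mesoderm-higher and 6 for non-mesoderm-higher pairs of comparison 1, and 16 and 4 in comparison 2. If each read pair was entered at both ends, a value of 6 stands for 3 read pairs and a value of 4 for 2 read pairs. Of the non-mesoderm-higher pairs, 85.2% in comparison 1 and 91.9% in comparison 2 lay at the minimum contact value of their list. Library totals were unknown, so a value listed at 0 cannot be read as absence of the contact.

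Mesoderm-higher pairs formed the majority in comparison 1 and the minority in comparison 2. In comparison 1, 143227 pairs were higher in mesoderm (77.4%, 95% Wilson interval 77.2 to 77.5) and 41936 were higher in non-mesoderm. In comparison 2, 302097 pairs were higher in mesoderm (36.6%, 36.5 to 36.7) and 522581 were higher in non-mesoderm. The balance of gains and losses thus differed between the replicate comparisons, beyond intervals that cover counting error only. The minimum contact values differed as well. They were 8 for mesoderm-higher and 6 for non-mesoderm-higher pairs in comparison 1, and 12 and 4 in comparison 2. A setting chosen after seeing the data gave both directions the same minimum contact value. The mesoderm-higher share was then 98.7% in comparison 1 and 99.9% in comparison 2. This setting removed most non-mesoderm-higher pairs by construction and left 1951 and 179 of them. An equal contact value is also not an equal threshold if the libraries differ in depth. These shares therefore do not measure the balance of gains and losses.

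The direction of a changed contact depended on the distance it spanned, in the same order in both comparisons. Mesoderm-higher contacts were short. Their median distance was 12 kb (interquartile range 6 to 26) in comparison 1 and 25 kb (13 to 46) in comparison 2. Non-mesoderm-higher contacts spanned a median of 51 kb (22 to 117) in comparison 1 and 496 kb (174 to 2099) in comparison 2, which was 4.25 and 19.8 times as far. Of the non-mesoderm-higher contacts, 28.8% and 85.8% reached beyond 100 kb, against 2.31% and 5.49% of the mesoderm-higher ones. Between 2 and 20 kb at least 87.2% of the listed pairs were mesoderm-higher in every distance band of both comparisons. The share was close to even at 51 to 100 kb, with 54.3% and 53.7%, and fell to 1.53% and 0.0152% beyond 1000 kb.

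Contacts between directly neighbouring bins departed from this order. Only 48.1% of them were mesoderm-higher in comparison 1 and 22.1% in comparison 2, whereas at 2 kb the shares were 97.6% and 89.4%. With the same minimum contact value for both directions, the distance order was much weaker in comparison 1 and did not hold in comparison 2. The ratio of medians was then 1.17 in comparison 1 and 0.04 in comparison 2, which turned the direction in the latter. This setting left 1951 non-mesoderm-higher pairs in comparison 1 and 179 in comparison 2, of which 481 and 104 joined neighbouring bins. A sign test over 2 comparisons cannot reach p below 0.05. By the depth proxy the non-mesoderm library was the shallower one in both, so a distance order found in both does not separate population from depth.

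**Figure D1:**
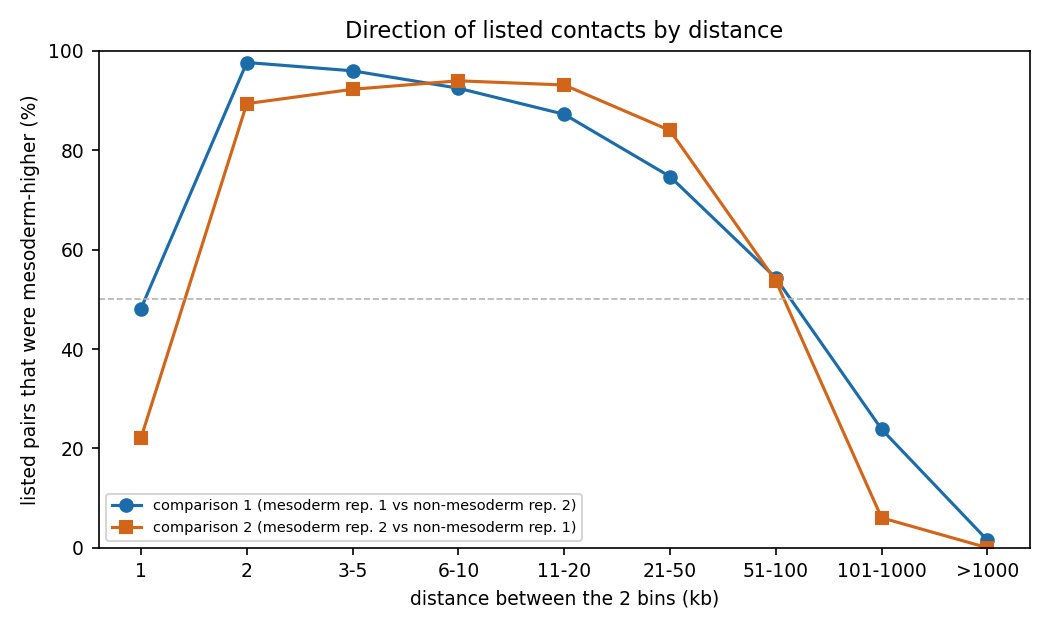
Percent of listed bin pairs that were mesoderm-higher (vertical axis) by the distance between the bins in kb (horizontal axis, unequal bands), with circles for comparison 1 and squares for comparison 2. At 2 kb the shares were 97.6% and 89.4%, at 51 to 100 kb 54.3% and 53.7%, and neighbouring bins at 1 kb lay at 48.1% and 22.1%; the dashed line marks 50%, and the direction rests on the order in the lists' names.

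The X chromosome carried fewer of the non-mesoderm-higher contacts than its share of bins in both comparisons, and more of the mesoderm-higher ones, clearly so in comparison 1 alone. X held 19.7% of the bins. It held 26.0% of the mesoderm-higher and 13.8% of the non-mesoderm-higher pairs in comparison 1, and 20.8% and 15.7% in comparison 2. In comparison 2 the arms 3L and 3R, each with 20.2% of the bins, held 23.0% and 21.8% of the mesoderm-higher pairs, a larger excess than that of X. Of the listed pairs on X, 86.6% were mesoderm-higher in comparison 1 and 43.4% in comparison 2, the highest share among the arms 2L, 2R, 3L, 3R and X in both. Arm 2R had the lowest share in comparison 2, at 28.2%, and 3R in comparison 1, at 73.2%. Chromosome 4 contributed 85 pairs in comparison 1, all mesoderm-higher, and 25 in comparison 2, of which 15 were mesoderm-higher. The adjusted number per unit of contact value was larger on X than on the autosomal arms in all 4 libraries, so that mesoderm-higher pairs were listed from a contact value of 8 on X in comparison 1, against 10 on the arms of chromosomes 2 and 3. In comparison 2 this minimum was 12 on X, 14 on 2L, 3L and 3R, and 16 on 2R. The share of all pairs lying on X was 23.2% in comparison 1 and 17.5% in comparison 2. In lists of equal length it was 52.2% in comparison 2, where the cut by score favours X through its larger adjusted numbers.

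Some contacts were listed in both comparisons, and most of these were mesoderm-higher in both. By the depth proxy the non-mesoderm library was the shallower one in both comparisons, so a recurring direction does not separate population from depth. The lists shared 18444 bin pairs, 9.96% of list 1 and 2.24% of list 2. This was 2.07 times the mean of 8931 under circular shifts (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). The shifts do not keep the number of listed pairs at a bin, and against the overlap computed from those numbers the excess was 1.19 times. Of the shared pairs 16776 (91.0%) changed in the same direction, against a mean of 80.7% and a maximum of 82.2% under the shifts (permutation p = 0.000999, likewise the smallest) and 87.7% when computed from listed pairs per bin. Pairs that were mesoderm-higher in both comparisons numbered 16285 and had a median distance of 14 kb (interquartile range 7 to 25). Pairs that were non-mesoderm-higher in both numbered 491, with a median distance of 3 kb (1 to 73.5).

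The 4 combinations of direction differed in how they stood to the shifts. Shared mesoderm-higher pairs were 2.34 times the shifted mean of 6959, and shared non-mesoderm-higher pairs 1.97 times the shifted mean of 249.7. Pairs that were mesoderm-higher in comparison 1 and non-mesoderm-higher in comparison 2 numbered 155, or 0.210 times the shifted mean. The opposite change was found for 1513 pairs, 1.54 times the shifted mean but 0.951 times the overlap computed from listed pairs per bin. Against that computed overlap, the excess of shared mesoderm-higher pairs was smaller, at 1.22 times, while that of shared non-mesoderm-higher pairs was 1.98 times. Neighbouring bins made up 237 of the 491 shared non-mesoderm-higher pairs. The excess of these pairs was not computed without neighbouring bins, so it cannot be read as one of longer contacts. Within 100 kb, independent lists without regard to distance would share 3522 mesoderm-higher and 195 non-mesoderm-higher pairs, and 16115 and 404 were found. By the same reckoning 136 pairs against 914 were mesoderm-higher in comparison 1 alone, and 1456 against 751 in comparison 2 alone.

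**Figure D2:**
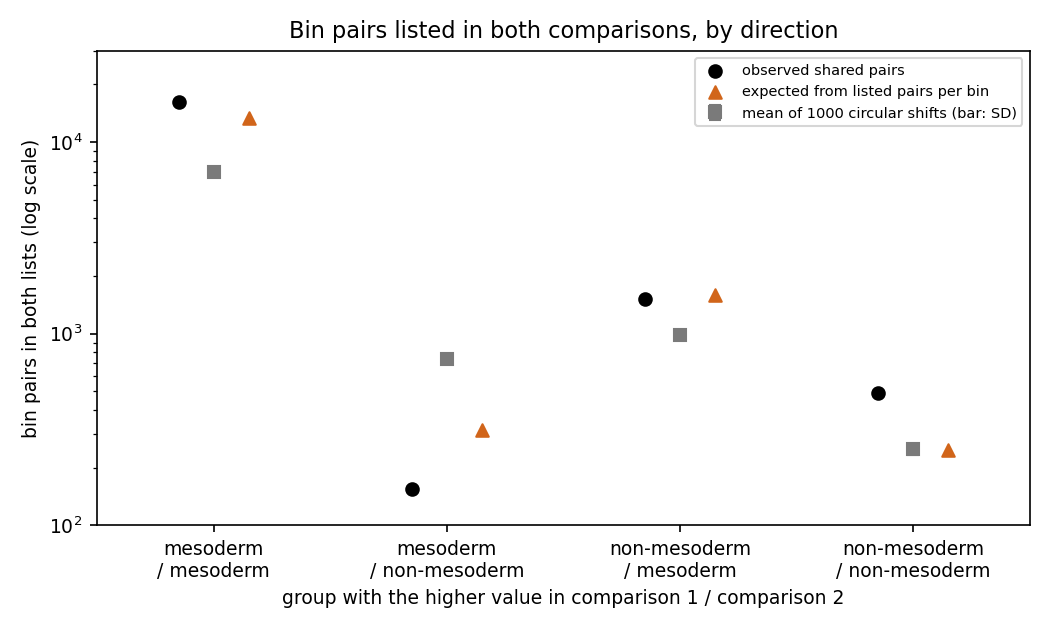
Number of bin pairs present in both lists (vertical log axis) for each combination of the population with the higher value in comparison 1 and comparison 2, with circles for observed counts, squares for the mean of 1000 circular shifts with SD bars smaller than the symbols, and triangles for the overlap computed from listed pairs per bin. The 16285 pairs that were mesoderm-higher in both lay above both expectations, and the 155 pairs that changed from mesoderm-higher to non-mesoderm-higher lay below both; the direction rests on the order in the lists' names.

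Contacts of neighbouring bins kept their direction almost without exception. Of 309 neighbouring-bin pairs in both lists, 237 were non-mesoderm-higher in both, 68 were mesoderm-higher in both and 4 changed direction. The same-direction share was thus 98.7%, and it was 98.0% (841 shared pairs) at 2 kb, 91.5% (4972) at 11 to 20 kb and 77.1% (332) between 100 and 1000 kb. The agreement that the direction splits alone would give differs by band and was not computed. At 2 kb 97.6% and 89.4% of the listed pairs were mesoderm-higher, against 48.1% and 22.1% for neighbouring bins. The fall with distance is therefore not read as a loss of reproducibility. Neighbouring bins made up 237 of the 491 pairs that were non-mesoderm-higher in both comparisons.

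Shared mesoderm-higher contacts touched 23782 bins. Of these, 17641 had 1 such contact, 4359 had 2, and a few bins on several arms had many. The bin X 602001 to 603000 had the most, with 10 shared mesoderm-higher partners between 558001 and 649000. At this bin 23 of 24 listed pairs were mesoderm-higher in comparison 1 and 27 of 29 in comparison 2. Bins with 9 such partners were 3R 10270001 to 10271000 (partners 2 to 52 kb away), X 19255001 to 19256000 (6 to 89 kb) and 2R 4182001 to 4183000 (12 to 35 kb). These 4 bins exceeded the highest count at any bin in 100 shifts, which was 8 (permutation p = 0.00990 for the highest count, the smallest that 100 shifts can give), under shifts that do not keep the listed pairs per bin. The other named bins had 8 shared partners each. They were 2L 21034001 to 21035000, 3R 12569001 to 12570000, X 2955001 to 2956000, X 7077001 to 7078000, 3L 20849001 to 20850000 and 3R 26488001 to 26489000. Around 3R 12569001 to 12570000 the partners stretched from 12535001 to 12658000, and all 23 listed pairs of comparison 1 and 24 of 33 in comparison 2 were mesoderm-higher. The farthest partner of 3L 20849001 to 20850000 lay 145 kb away. None of the 10 named bins was among the 10 highest when the count was divided by the listed pairs at the bin. That ranking was led by a bin with 1 shared pair of 2 listed, and its 10 highest bins had 2 to 16 listed pairs. Low numbers of listed pairs thus decide it, and it does not test the named bins.

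No bin had more than 2 shared non-mesoderm-higher contacts. Of 973 bins with such a contact, 964 had 1 and 9 had 2, and the highest count under the shifts was also 2 (permutation p = 0.762). With 491 such pairs the counts per bin were too low to compare with those of the 16285 mesoderm-higher pairs. Bins with 2 included 3R 13198001 to 13199000, 2L 18481001 to 18482000 and 2R 13872001 to 13873000, whose shared partners were their direct neighbours. At 3R 24082001 to 24083000 the shared partners lay 3 and 172 kb away, and at 3R 6977001 to 6978000 they lay 2 and 338 kb away. At 2L 213001 to 214000 they lay 65 and 118 kb away. The remaining bins with 2 were 2L 5724001 to 5725000, 3L 19080001 to 19081000 and 2R 6452001 to 6453000, and the tenth named bin, with 1, was 2L 6833001 to 6834000.

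The shared pairs with the largest changes spanned 2 to 29 kb where mesoderm-higher and 1 kb where non-mesoderm-higher. In the authors' deposited table, the contact of 3L 2941001 to 2942000 with 2943001 to 2944000 had a contact value of 100 in mesoderm replicate 1 and 58 in mesoderm replicate 2, and 0 in both non-mesoderm libraries. Of the 5 leading mesoderm-higher pairs in the authors' deposited table, 4 lay on X, where the same contact value gave a larger adjusted number and so a higher rank. In the authors' deposited table, X 3574001 to 3575000 with 3576001 to 3577000 had values of 42 and 48 in mesoderm replicates 1 and 2, and X 12587001 to 12588000 with 12589001 to 12590000 had 40 and 46, all against 0. In the authors' deposited table, X 4815001 to 4816000 with 4823001 to 4824000 and X 12610001 to 12611000 with 12639001 to 12640000 each had 40 and 54 against 0, over 8 and 29 kb. All 5 leading non-mesoderm-higher pairs joined neighbouring bins. In the authors' deposited table, 2L 6833001 to 6834000 with its right neighbour had values of 10 and 18 in non-mesoderm replicates 1 and 2, against 0 in both mesoderm libraries. The values of non-mesoderm replicates 1 and 2 in the authors' deposited table were 6 and 16 at X 4359001 to 4360000, 8 and 18 at 3L 10285001 to 10286000 and 8 and 14 at X 9532001 to 9533000, against 0. In the authors' deposited table, 2R 8941001 to 8942000 had 10 and 18 in these libraries, against 2 in mesoderm replicate 2 and 0 in mesoderm replicate 1.

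The balance of direction varied along the arms in a way that recurred between comparisons. In 115 windows of 1 Mb, the mesoderm-higher share of comparison 1 was related to that of comparison 2, with Spearman's rho 0.578 (permutation p = 0.0001, the smallest the permutations can give, adjusted p = 0.00035) and Pearson's r 0.527 (permutation p = 0.0001, adjusted p = 0.000525). Without the 2 windows farthest from the median of comparison 1, r was 0.525. Windows are not independent replicates. The number of listed pair ends differed between windows as well. On 3R the lowest share of comparison 1 (58.3%, 23 to 24 Mb) came with 2344 ends and the highest (80.1%, 12 to 13 Mb) with 4402. The 3R window with the fewest ends, 394 at 4 to 5 Mb, stood at 71.3%. Whether local contact density accounts for the recurrence was not tested, and the rotations do not allow for it. On the autosomal arms alone rho was 0.528 and r was 0.468 (92 windows, permutation p = 0.0001 for each, adjusted p = 0.00035 and 0.000525). Within single arms rho was 0.840 on 2L, 0.691 on 3R, 0.573 on 2R, 0.460 on 3L and 0.384 on X. The adjusted permutation p of rho was 0.0316 on 2L, 2R and 3R and 0.0512 on 3L and X. A single arm of 22 to 24 windows has few distinct rotations. The unadjusted permutation p of rho on 2L, 2R and 3R (0.0218 to 0.0241) thus lay near the smallest possible. Whether an arm passed in 1 Mb windows is therefore a coarse call. Pearson's r within arms was 0.779 on 2L and 0.745 on 2R (adjusted permutation p = 0.0389 for each), 0.429 on 3R (0.187), 0.404 on 3L (0.117) and 0.294 on X (0.136), so in 1 Mb windows the relation on 3R passed by rank alone. On 2R r was 0.438 without the 2 windows farthest from the median. In windows of 100 kb, rho was lower, at 0.417 over all arms, 0.302 on the autosomal arms, 0.432 on 2L, 0.407 on 3R, 0.378 on X, 0.291 on 3L and 0.181 on 2R. With these more numerous windows every arm passed by rho (adjusted permutation p from 0.00513 to 0.0392) and by r, which was 0.432 on 3R (adjusted permutation p = 0.0113). With pairs within 100 kb alone, chosen after seeing the data, rho was 0.302 over all arms, 0.442 on the autosomal arms and 0.151 on X (adjusted permutation p = 0.265 on X), and r over all arms was 0.157 (adjusted permutation p = 0.00761). On 3R the adjusted permutation p of rho was then 0.0659. With these pairs no single arm passed by r, which was 0.419 on 2L (adjusted permutation p = 0.0955), 0.326 on 2R (0.163) and -0.035 on X (0.788).

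A stretch of 3R stood low in both comparisons. From 23 to 24 Mb 58.3% of the listed pair ends were mesoderm-higher in comparison 1 and 30.3% in comparison 2. From 22 to 23 Mb the shares were 62.6% and 27.7%, and from 21 to 22 Mb 66.2% and 24.3%. In the order given, these windows held 2344, 2259 and 2419 listed pair ends in comparison 1. The medians over the 3R windows were 72.6% and 35.9%. In comparison 2 other 3R windows lay below that of 23 to 24 Mb, such as 20 to 21 Mb at 28.9% and 14 to 15 Mb at 29.0%. On 2L the window from 17 to 18 Mb was low as well, with 62.7% and 28.6% against medians of 74.2% and 35.8%. It was the lowest of 2L in comparison 1 only. In comparison 2 the 2L window from 22 to 23 Mb stood lower, at 20.4%. The window at the start of 2R had 65.9% in comparison 1 and 6.08% in comparison 2. It held only 659 listed pair ends in comparison 1, against 2478 in the next window, and the cause of its low shares was not tested. These windows were chosen after their values were seen.

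**Figure D3:**
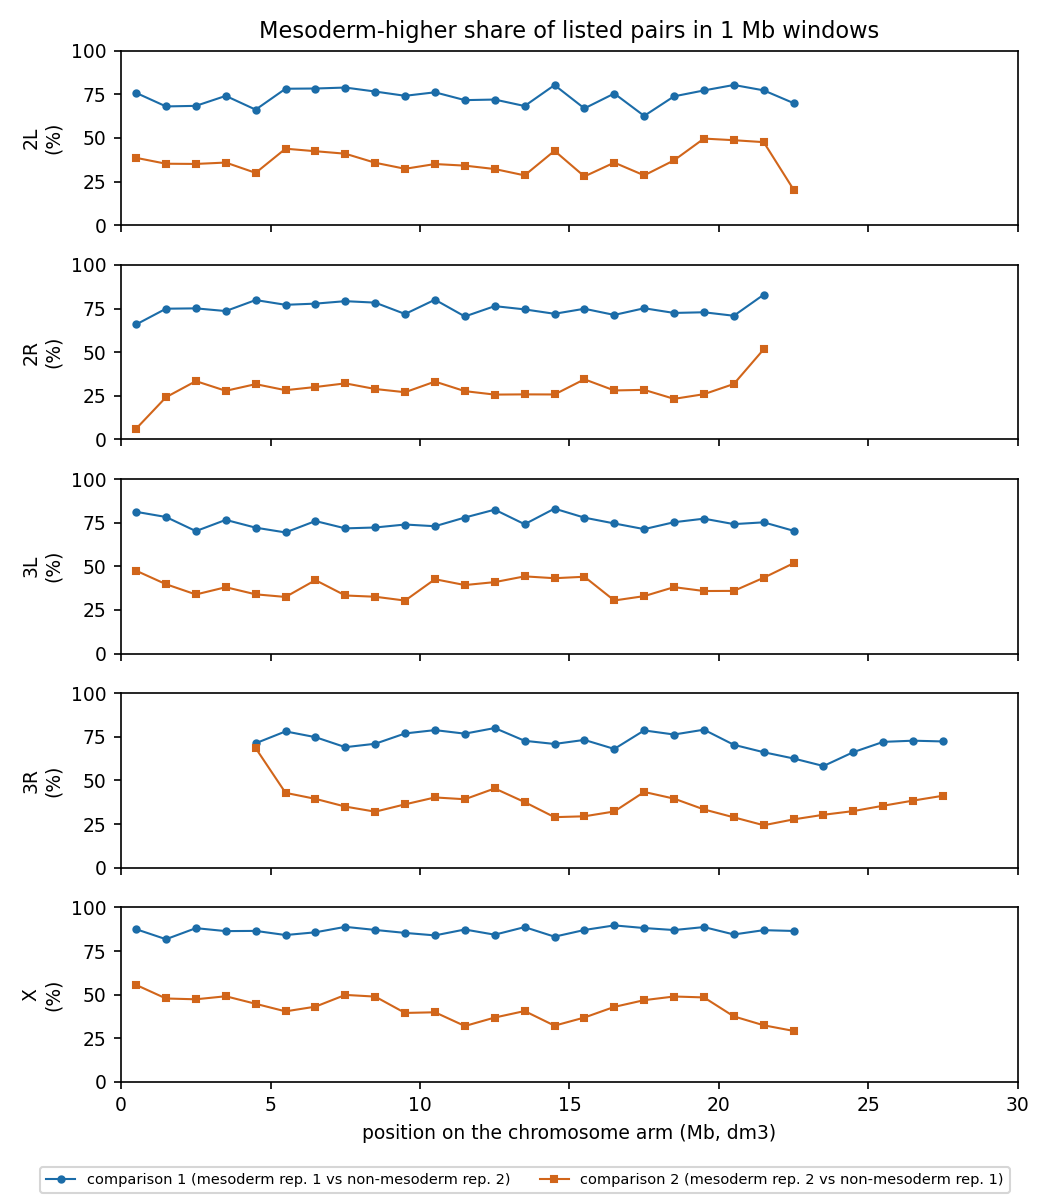
Percent of listed pair ends that were mesoderm-higher (vertical axes) in 1 Mb windows along 2L, 2R, 3L, 3R and X (horizontal axis, position in Mb of dm3), with circles for comparison 1 and squares for comparison 2. The comparisons differ in level, with medians of 75.9% and 35.8%, and on 3R both are low from 21 to 24 Mb; the direction rests on the order in the lists' names.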

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

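The alternatives with the same minimum contact value, with the expectation per bin, without neighbouring bins (for results other than distance) and over windows were chosen after seeing the data. Under the alternatives that shift both ends together the overlap was 1.32 to 2.42 times its expectation, and against the expectation per bin, which alone allows for uneven bins, it was 1.19 times. Ends shifted independently gave 289 times, an excess fixed by the loss of distance. The direction agreement stayed past its shifted value (84.8% to 99.5%). The 99.5% came with the same minimum contact value, where 98.7% and 99.9% of the listed pairs were mesoderm-higher and agreement was nearly fixed. With larger changes only, the lists held 101785 and 455531 pairs and shared 8001, the mesoderm-higher share was 89.0% and 30.8%, and X held 24.6% and 26.3% of the pairs. Fewer pairs remain by construction, and the cause of the other shifts was not tested. With lists of equal length, for which the score replaced p values, comparison 2 held 185163 pairs, 36.9% of them mesoderm-higher and 52.2% on X, and 7350 were shared. With the same minimum contact value, comparison 2 held 302276 pairs, the mesoderm-higher share was 98.7% and 99.9% (reversed in comparison 2), the ratio of median distances was 1.17 and 0.04 (reversed in comparison 2), and X held 26.2% and 20.8%. This setting removes most non-mesoderm-higher pairs by construction. Without neighbouring bins the mesoderm-higher share of comparison 1 was 77.8%. With ends within 1 bin, 78668 pairs were shared. With counts divided by the listed pairs at a bin, 0 of the 10 named bins were kept among the 10 highest, a ranking led by bins with few listed pairs. Taking the mean of both comparisons (57.0% mesoderm-higher), leaving out any 1 library leaves 1 comparison, and the share ranged from 36.6% to 77.4%. It reversed to 36.6% without mesoderm replicate 1 or non-mesoderm replicate 2, and the cause was not tested. The same range was 4.25 to 19.8 for the distance ratio and 17.5% to 23.2% for X. In all, 59 values under alternatives were counted as kept, 19 as moved and 4 as reversed. A value counted as kept could still differ in size. Examples are the overlap against the expectation per bin (1.19 times) and the distance ratio of each comparison alone (4.25 and 19.8). Values of comparison 1 with lists of equal length were counted as kept too, but could not change because list 1 was not cut. A stricter p, the fixed gene lists and their window were not run, and a limit to single arms removed no pair. No paired analysis was possible because the lists give only crossed comparisons of replicate 1 with replicate 2 and no values of single libraries outside them. Library depth is unknown, and changes below the minimum contact values of the lists were not seen here.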

Other observations

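The tests of contact density, of the minimum contact value and of whole bins were chosen after the patterns had been seen. A pair of adjacent bins on 3R had the most listed contacts of comparison 2. The bin 3R 24310001 to 24311000 had 190 listed pairs in comparison 2, 129 of them non-mesoderm-higher, and 3R 24311001 to 24312000 had 150, 113 of them non-mesoderm-higher, against a median of 16 over bins. Over the whole list 522581 of 824678 pairs were non-mesoderm-higher. In comparison 1 the bin 3R 24311001 to 24312000 had 26 listed pairs, 20 of them non-mesoderm-higher, against a median of 3 and 41936 of 185163 non-mesoderm-higher pairs over the list. The bin with most listed pairs in comparison 1 was X 1057001 to 1058000, with 29 pairs, 28 of them mesoderm-higher. On 3L the bins 6952001 to 6953000 and 6954001 to 6955000 had 87 and 74 listed pairs in comparison 2, of which 67 and 63 were non-mesoderm-higher.

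Among pairs of comparison 1 at least 2 kb long, matched on chromosome, distance and contact value, 11871 of 103484 mesoderm-higher pairs recurred as mesoderm-higher in comparison 2, and 88 of 1468 non-mesoderm-higher pairs did. The matched rate ratio was 1.74 (95% interval 1.42 to 2.12). For the matched pairs this argues against contact density as the whole cause of the recurrence. They included only 1468 of the 41936 non-mesoderm-higher pairs listed at any distance, since most of those lay below the contact values of mesoderm-higher pairs. By arm the interval included 1 on 2R (0.718 to 2.29) and 3L (0.811 to 2.70) and lay above 1 on 2L, 3R and X. Pairs moved by 1 kb already gave 1.09 (0.903 to 1.31), and pairs moved by 2 to 5 kb gave 1.16 (1.05 to 1.29). Pairs moved by 11 to 20 kb gave 1.09 (1.03 to 1.15). All of these lay below the interval of 1.42 to 2.12, so most of the excess was confined to the identical pair of bins. This argues against a difference spread over the surrounding region as the whole cause, again for the matched pairs. For pairs that were mesoderm-higher in both comparisons, the overlap computed from each bin's number of listed pairs was 82.0% of the observed one, so uneven bins may account for most of it, and these remain open. A difference in contacts between mesoderm and other cells is a further hypothesis. These lists alone cannot separate it from a bin-level one or from the difference in depth read from the proxy.

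Mesoderm-higher pairs spanned shorter distances in both comparisons, but the lists took non-mesoderm-higher pairs from lower contact values. At equal chromosome and contact value the ratio of median distances was 0.795 in comparison 1 and 0.106 in comparison 2. Without neighbouring bins it was 1.48 and 0.646. Only 1886 of 41936 and 137 of 522581 non-mesoderm-higher pairs could be matched in this way, which is too few to decide. Over all listed pairs the ratio was larger in comparison 2 (19.8 against 4.25), where the depth proxy also differed more (4.23 against 1.62 times). It therefore stays open whether the distance pattern came from the minimum contact values, from the difference in depth or from the tissues.

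For neighbouring bins the direction recurred in both populations. Of matched pairs in comparison 1, 81 of 481 non-mesoderm-higher pairs recurred as non-mesoderm-higher, against 3 of 667 mesoderm-higher pairs (matched rate ratio 29.1, 95% interval 3.32 to 255), which argues against contact density. In the same strata 41 of 667 mesoderm-higher pairs recurred as mesoderm-higher and 0 of 481 non-mesoderm-higher pairs did. At the bins of the 237 shared non-mesoderm-higher pairs, the other listed pairs were non-mesoderm-higher 1.02 times as often as all pairs of the same distance in comparison 1 (0.910 to 1.13) and 0.953 times in comparison 2 (0.927 to 0.980). This argues against loss of the whole bin in mesoderm for bins with other listed pairs. Bins without them could not be judged, such as 2L 6833001 to 6834000, with 1 listed pair in each comparison. Local differences in chromatin or in DpnII cutting between the sorted populations stay open and may be followed up at these bins, since neither was tested.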
